A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

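Insertions of the Ty5 transposon were profiled in 16 libraries, 1 per group, with the calling-card assay. Per the labels, each strain carried a plasmid with a Sir4-tagged factor under the ADH1 promoter and a second plasmid with Ty5 under the inducible GAL1/10 promoter, and insertion sites were recovered by inverse PCR after digestion with 3 restriction enzymes. The submitters' processing notes name Novoalign and the sacCer2 build without a tool version, and versions of other tools are not given there. Groups were taken from the labels, as 12 factor libraries and 4 Gal4 libraries from strains with a further deletion.

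The authors deposited a table per library in which each region between neighbouring genes has a count of insertions in the library and a count in a background set. Per the file headers, further columns hold each count as a fraction of its total, a p-value of a hypergeometric test, a p-value of a Poisson test and the same values for wider regions. On recomputation from the counts, the deposited hypergeometric p-value differed by at most 3.26e-08, and the Poisson p-value fitted a mean with 0.2 added. A deposited log2 column holds the log2 of the library's scaled fraction and was not used in tests. Log2 ratios between libraries were computed here from the authors' counts with 0.5 insertions added.

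A background of 84109 insertions is used in 15 tables and another of 103922 in the Gal4 table, and these correlated with r = 0.939 across shared regions. The 15 tables list 4748 regions, from which 8 mitochondrial and 2-micron plasmid regions were left out, and the Gal4 table lists 4532. Comparisons between libraries used the 4383 regions with the same flanking genes in all tables, 22 of which differ in length by over 20 bp between the tables. Edges equal to gene ends of the R64 assembly were found for 99.4% of regions in the 15 tables, against 13.8% in the Gal4 table, although the notes name a single build. Coordinates printed are those of the 15 tables, unconverted. Gene names came from the tables and from a gene table of the R64 assembly, by which 846 shared regions (19.3%) hold another gene between the flanking ones. By gene orientation, 1123 shared regions hold no promoter, 2127 hold 1 and 1133 hold the promoters of both neighbours.

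Calls, list values and tests were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. A region was called where the authors' hypergeometric p was 0.001 or less and the library held at least 5 insertions there. Lists were pooled as shares of all insertions in the library over the share of the background, with exact conditional binomial intervals, and each list's median was placed among 10000 random lists of the same size matched on background insertions, or on mean insertions of both libraries in the deletion comparisons. Lists made of Gal4-called regions tend to rank low in the latter, so their percentiles are not reported. Shares of a library sum to a fixed total, so folds below 1 at unbound regions follow from insertions taken up elsewhere. Overlaps were set beside the product of both numbers of called regions over the 4383 regions, and simulated libraries drawn from the background had too few calls to serve as a second comparison. Each Gal4 library with a further deletion was compared with the Gal4 library region by region with a two-sided Fisher's exact test, for regions with at least 10 insertions in both libraries together, with Benjamini-Hochberg adjustment and a threshold of 0.05. The same test compared the pooled Gal4 targets between the 5 Gal4 libraries, adjusted over 10 pairs. Similarity between the comparisons was measured by correlation and covariance of log2 ratios beside 100 simulated unchanged libraries. The seed was 20240, the floor for a fold was 3 insertions, and 1000 shuffles within 58 classes of background insertions and length were used for regions called for many factors.

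The design, the gene lists and most alternatives were fixed before the data were examined. Regions named were those of each factor's own target list, the 10 called regions with the most insertions per library, the 10 largest changes in each direction per deletion library, the regions of the deleted genes and the 10 regions called for the most factors. Genes without a region of their own in the tables were LEU2, YLL056C, YLR346C, ICL1, HXK1, HXT17, HIS3, LYS14 and URC2. The alternatives covered the threshold, the minimum of insertions, the p-value column, thinning to equal depth, the region definition, the scaling and the reference library. Binding-site sequences in called regions were to be counted, but no genome sequence was at hand, so that comparison was not run.

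Intervals cover counting error only. Insertions were recovered by PCR without molecular tags, and with 1 library per group neither biological nor technical variation could be estimated. The threshold was tested on simulated data. Simulated libraries drawn from the background gave 0.78 to 1.66 calls on average and at most 7. At the depth of Leu3, 41% of regions raised 4-fold and 99% of regions raised 16-fold were called, against 11% and 84% at the depth of hmo1Δ, and 0.0220% and 0% of unchanged regions. In the comparison with Gal4, regions raised 4-fold passed in 36% (hmo1Δ), 32% (leu3Δ), 54% (sef1Δ) and 38% (yrm1Δ) of cases, regions lowered to 0.25-fold in 14%, 18%, 14% and 8%, and unchanged regions in at most 0.671%. Absence of a call at a weak region, above all in the shallower deletion libraries, therefore says little.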

Results

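Calling-card profiling was collected for 12 zinc cluster transcription factors of budding yeast. Each factor was fused to Sir4, the silencing protein that recruits the integrase of the Ty5 retrotransposon, so that Ty5 inserted near the DNA sites the fusion occupied. The strains lacked SIR4 and their own chromosomal copy of the tagged factor, and insertion sites were recovered by inverse PCR after 3 restriction digests. Another 4 libraries held the Gal4 fusion in strains that also lacked HMO1, LEU3, SEF1 or YRM1. Each of the 16 groups had 1 library, so no value has a replicate error, and intervals are 95% intervals for counting error alone.

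The factor libraries held 33645 insertions for Gal4, 36063 for Leu3, 31359 for Yrm1, 28316 for Yrr1, 35692 for Tea1 and 23780 for Lys14. The others held 23937 for Cat8, 18295 for Cha4, 23769 for Put3, 27453 for Urc2, 18746 for Hal9 and 26176 for Aro80. Depth was lower in the Gal4 libraries with an extra deletion, at 6932 insertions for hmo1Δ, 9628 for leu3Δ, 13882 for sef1Δ and 10280 for yrm1Δ. Between 61.0% (Gal4) and 80.5% (Yrr1) of insertions fell between genes. Values are insertions per 100000 in the library, where 1 insertion is worth 2.77 (Leu3) to 14.4 (hmo1Δ), and the fold over background divides this share by that of the authors' background insertions. Regions carry the names of their flanking genes, and coordinates are those of the deposited tables, for which the submitters' processing notes name the sacCer2 build. A region was called at the authors' p of 0.001 or less with at least 5 insertions.

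Gal4, the activator of galactose metabolism, concentrated its insertions at the GAL genes. The promoter of GAL2, which encodes the galactose permease (EMP46/GAL2, chromosome XII 289250 to 290212), held 1781 insertions, 75.4-fold over background (59.6 to 96.6). GAL7/GAL10 (chromosome II 275527 to 276253) held 1410, a fold of 104 (76.3 to 145). The divergent GAL10/GAL1 promoter (chromosome II 278352 to 279021), a sequence also carried on the transposon plasmid, held 850, a fold of 125 (81.3 to 203). All 10 regions of the Gal4 target list were called, down to GCY1 at 4.49-fold and MTH1 at 2.30-fold (1.498 to 3.51). Strong regions outside the list were SRP40/PTR2 with 1096 insertions (38.9-fold), KTI12/HAP4 with 876 (21.8-fold), AGE1/SNA2 with 863 (26.9-fold) and STP4/SIT4 with 657 (26.0-fold). PTR2 encodes a peptide transporter and HAP4 an activator of respiratory genes. In all, 83 regions were called for Gal4, and they held 45.04% of its insertions (44.5 to 45.6) against 4.04% of the background.

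Leu3, which controls leucine and other branched-chain amino acid synthesis, was called at all 8 regions of its list. LEU1, encoding isopropylmalate isomerase (LEU1/PMA1, chromosome VII 478652 to 479910), led with 1086 insertions, 57.6-fold over background (42.6 to 79.7). ILV5, ILV3 and ILV2, which encode enzymes of isoleucine and valine synthesis, were at 20.03-fold, 14.98-fold and 14.3-fold, the amino acid permease gene BAP2 was at 17.3-fold and LEU4 at 9.78-fold. Weaker folds were found at BAT1 (7.34) and GDH1 (6.39), the gene of an ammonia-assimilating glutamate dehydrogenase. Regions outside the list with many insertions were PET9/YBL028C (692), VTC1/ALD5 (499), DIC1/ORM2 (425), FRS2/GAT1 (395) and MSN2/CCS1 (381, 32.9-fold). In total 108 regions were called, with 36.8% of the insertions.

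Yrm1 and Yrr1, related regulators of multidrug resistance genes, shared most of their strongest regions. The transporter genes AZR1, YOR1 and SNQ2 stood at 105-fold (66.5 to 175), 42.7-fold and 14.8-fold for Yrm1, and at 100.4-fold, 54.8-fold and 63.9-fold for Yrr1. SNG1 was at 40.2-fold for Yrm1 and 87.9-fold for Yrr1. FLR1, another drug transporter gene, held 115 insertions for Yrr1 (8.76-fold, 6.04 to 12.9) and none for Yrm1. The promoter of YRR1 itself held 15 insertions for Yrr1 (22.3-fold, 5.18 to 201) and none for Yrm1, and ATR1 and YRM1 held none in either library. Of the 8 regions in the shared target list, 4 were called for Yrm1 and 6 for Yrr1. The most used Yrm1 regions were RGI2/VHR1 (chromosome IX 248396 to 249991, 1386 insertions) and SRT1/YPK2 (chromosome XIII 469476 to 473420, 1161). The SRT1/YPK2 interval also spans LAF1 and YMR103C. For Yrr1 they were IME1/RPL43B (chromosome X 605651 to 608305, 1169 insertions) and ASK1/SFK1 (chromosome XI 340546 to 341312, 1087). Totals were 113 called regions for Yrm1 and 87 for Yrr1.

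Lys14, the activator of lysine synthesis, was called at all 7 LYS regions of its list. LYS20, encoding homocitrate synthase (YDL183C/LYS20, chromosome IV 131833 to 133437), held 1575 insertions, 52.6-fold over background (43.2 to 64.6). LYS12, LYS9 and LYS1 were at 107-fold, 76.9-fold and 69.6-fold, while LYS21 and LYS4 were at 18.0-fold and 9.16-fold. LYS2, an auxotrophic marker locus in this strain family, was at 158-fold, and the lysine permease gene LYP1, which was not in the list, at 56.1-fold. Cat8, which activates genes for growth on non-fermentable carbon, was called at 9 of 10 regions of its list. SFC1, encoding a mitochondrial succinate-fumarate carrier (RPL43B/SFC1, chromosome X 608858 to 609773), held 584 insertions, 93.3-fold (61.0 to 150). Within the list, genes of the glyoxylate cycle and gluconeogenesis followed, with MLS1 at 42.9-fold, MDH2 at 38.8-fold, PCK1 at 34.5-fold and FBP1 at 23.9-fold. CDA1/CDA2, outside the list, was at 45.1-fold. SIP4, which encodes another activator of these genes, held 12 insertions (3.83-fold, 1.55 to 9.59) and was not called at the authors' p used here. Called regions numbered 49 for Lys14 and 65 for Cat8.

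Cha4, the activator of serine and threonine catabolism, placed 1273 insertions in CHA1/VAC17 (chromosome III 16880 to 17290), 266-fold over background (175 to 426). CHA1 encodes the serine and threonine deaminase. It placed 1215 in the promoter of the serine synthesis gene SER3 (AIM9/SER3, chromosome V 321846 to 322686), a fold of 329 (204 to 566), whereas AGX1, the other listed target, held 4 (1.02-fold). Put3, the activator of proline use, placed 1004 insertions at PUT1 (RRN5/PUT1, chromosome XII 424774 to 425186; 115-fold, 80.2 to 170) and 79 at PUT2 (140-fold, 37.4 to 1174). The proline permease gene PUT4 held 25 Put3 insertions, at background level (1.03-fold, 0.631 to 1.62). Aro80, the regulator of aromatic amino acid catabolism, was called at all 4 regions of its list. ARO10 (chromosome IV 1233517 to 1234218) held 1826 insertions (489-fold, 279 to 948), ARO9 1095 (352-fold), ESBP6 1523 (306-fold) and the promoter of ARO80 itself 66 (42.4-fold, 17.3 to 135). Called regions numbered 30 for Cha4, 26 for Put3 and 67 for Aro80.

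For Urc2, a regulator of uracil catabolism, 4 of the 10 regions with the most insertions held genes of pyrimidine metabolism, a grouping made after the values were seen. URA2, which encodes the entry enzyme of pyrimidine synthesis (URA2/TRK1, chromosome X 172367 to 173599), held 432 insertions (27.6-fold, 20.4 to 38.0). The uridine and uracil permease genes FUI1 and FUR4 were at 16.4-fold and 18.8-fold, and the salvage enzyme gene FUR1 at 53.2-fold. ARB1/PHM8 (423 insertions, 118-fold, 65.2 to 238), CBK1/YGP1 (277) and ZWF1/NAR1 (249) ranked directly after URA2. Tea1, a regulator named for its effect on Ty1 enhancers, had its most insertions at the glutamine synthetase gene GLN1 (ARP7/GLN1, chromosome XVI 640958 to 642208, 1181 insertions, 32.0-fold). HXT9/REE1 was at 77.5-fold for Tea1, YAP5/MUC1 at 72.1-fold and the transaminase gene BAT2 at 46.7-fold. Hal9, a factor linked to salt tolerance, placed 1681 insertions at the polyamine transporter gene TPO1 (FRA1/TPO1, chromosome XII 83710 to 84804), a fold of 164 (122 to 225). OYE2 followed at 83.8-fold, and the transporter gene PDR15 was at 12.2-fold. The sodium pump gene ENA1, the only listed Hal9 target, held 1 insertion, below background (0.145-fold, 0.00355 to 0.868). Called regions numbered 51 for Urc2, 113 for Tea1 and 97 for Hal9.

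Each target list was then compared across the 12 factor libraries, which asks whether a library carries the binding of its own factor. Pooled over its list, the own-factor fold was 35.2 for Gal4 (31.7 to 39.0), 18.0 for Leu3, 30.5 for Yrm1, 52.5 for Yrr1 and 51.1 for Lys14. It was 20.6 for Cat8, 147 for Cha4 (107 to 206), 32.9 for Put3 and 337 for Aro80 (250 to 466). The highest fold of any other library at the same lists was 2.90 for the Gal4 targets (Urc2), 2.72 for the Leu3 targets (Tea1), 1.16 for the Yrm1 and Yrr1 targets, 1.18 for the Lys14 targets and 2.42 for the Aro80 targets. Tea1 was an exception, with folds of 13.7 at the Cha4 targets, 13.1 at the Put3 targets (mostly PUT4/CIN1, 643 insertions) and 5.89 at the Cat8 targets (mostly SRY1/JEN1, 784 insertions). Yrm1 and Gal4 were exceptions too, reaching 12.96 and 6.92 at the Put3 targets, and PUT4/CIN1 held 497 Yrm1 insertions. The list medians of the own factors, Hal9 aside, lay at the 99.9th percentile or above among 10000 random lists matched on background insertions. Tea1 and Urc2 had no list fixed beforehand.

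**Figure D1:**
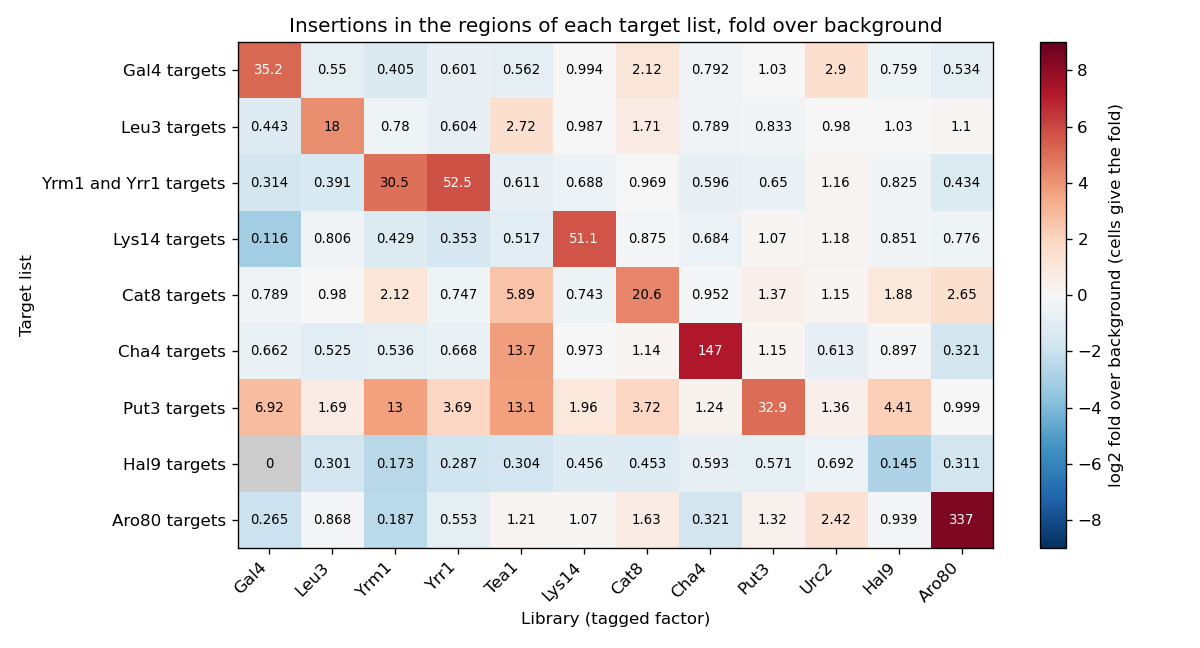
Fold over background (colour on a log scale, grey for 0 insertions, value printed in each cell) of the pooled insertions in 9 target lists (vertical axis) in each of the 12 factor libraries (horizontal axis). Own-factor cells run from 18.0 (Leu3) to 337 (Aro80), except Hal9 at ENA1 (0.145).

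The factors were next compared with each other, to ask whether zinc cluster proteins occupy the same promoters. Of 4383 regions present in every table, 504 were called for at least 1 factor, 335 for exactly 1 and 22 for 5 or more. The region between the sphingolipid gene IPT1 and SNF11 (chromosome IV 591344 to 592439) was called for 8 factors, and SRT1/YPK2, VMA13/YPR036W-A, PUT4/CIN1 and SOD1/ADO1 for 7 each. STP4/SIT4, TPO4/MOD5, PDR16/ELA1, ARG80/MCM1 and DOT6/PTC2 were called for 6 each. Yrm1 and Yrr1 shared 48 regions where independent lists would share 1.92, the strongest ratio of the 66 pairs (25.05). Gal4 shared 29 regions with Hal9 (1.66 for independent lists), 23 with Leu3 (1.85) and 21 with Yrm1 (1.87), and 47 of its 78 called regions in the shared set (60.3%) were called for another factor (8.42). The values for independent lists treat all 4383 regions as equally likely to be called, whatever their length and background. Lys14 (27.9%) and Put3 (30.8%) shared the least, and Yrm1 (77.1%), Hal9 (74.2%) and Yrr1 (71.3%) the most.

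In 63 of the 66 pairs the overlap exceeded that of independent lists, with a median ratio of 7.55, but no pair was matched on background or length. The 3 others, Put3 paired with Leu3, Cha4 or Urc2, shared no region. Without the 10% of regions with the most background insertions, 25 of 78 regions remained called for Gal4, and 7 of them (28%) were called for another factor, against 1.63 for independent lists. Yrm1 and Yrr1 kept 49 and 45 called regions and shared 24, against 0.56. Many called regions of these factors thus had high background, so part of the excess over independent lists may reflect where a call was possible.

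**Figure D2:**
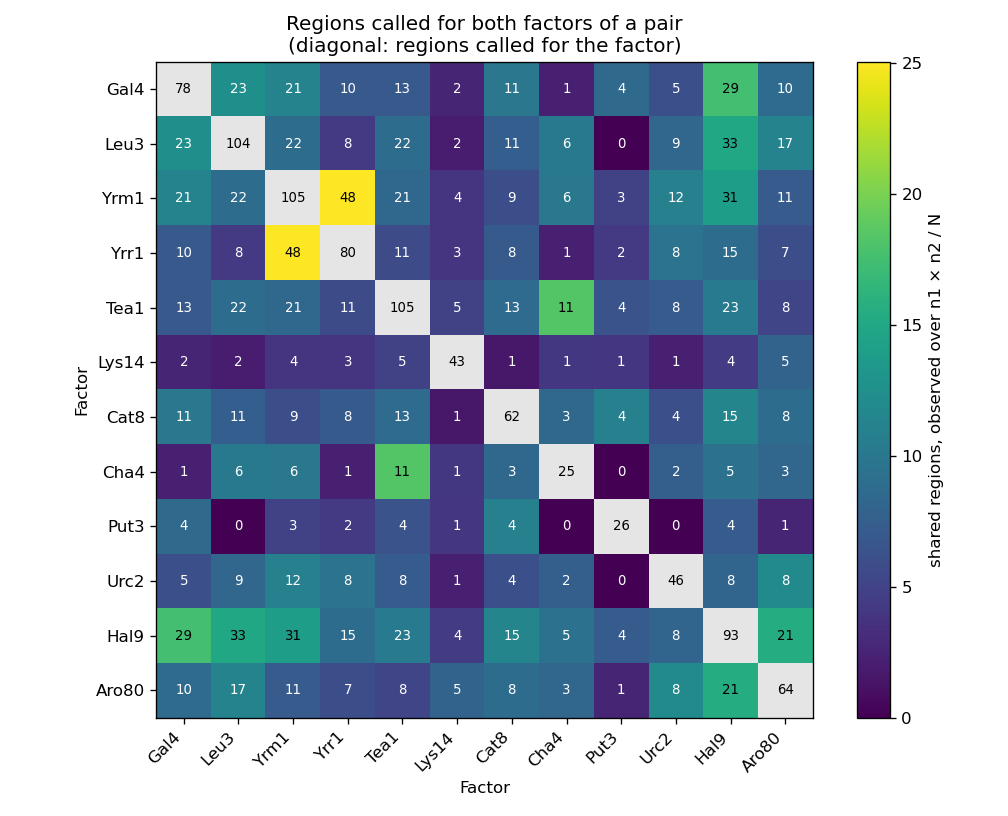
Number of regions called for both factors of each pair among the 12 factor libraries, with the factor's own number of called regions on the diagonal; colour shows the number over that of independent lists. Yrm1 and Yrr1 share 48, and Gal4 shares 29 with Hal9.

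The Gal4 libraries with an extra deletion ask whether Gal4 occupancy depends on the missing protein. Hmo1 is a high mobility group protein of ribosomal gene promoters, and Leu3, Sef1 and Yrm1 are zinc cluster factors. The labels give each of these libraries its own strain name, so strain and deletion are confounded. The promoters of GAL4, LEU3, YRM1 and SEF1 held 0 to 3 insertions in each of the 5 Gal4 libraries, and since a deletion leaves the promoter in place these counts do not check the labels. Regions were tested 1 by 1 against the Gal4 library with Fisher's exact test, which compares libraries and not conditions. The median ratio over regions with 10 or more insertions in both libraries was above 1 in each comparison, by 0.27 (hmo1Δ), 1.03 (leu3Δ), 0.36 (sef1Δ) and 0.32 (yrm1Δ) on the log2 scale, and results that turn when scaled to it are named as such. A minimum of 10 in the shallower library favours regions with a high ratio, so this scaling may overcorrect. Over all tested regions the median log2 ratio was 0.02 (hmo1Δ), 0.67 (leu3Δ), 0.26 (sef1Δ) and 0.05 (yrm1Δ).

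In the library labelled leu3Δ, insertions at the Gal4 targets were at background level. The 10 target regions together held 38 insertions, 1.003-fold over background (0.697 to 1.41), and their share was 0.0290 of that in the Gal4 library (0.0205 to 0.0399). EMP46/GAL2 fell to 7 insertions against 1781 (ratio 0.0137, 0.00551 to 0.0284; adjusted p = 7.84e-183, two-sided Fisher's exact test). GAL10/GAL1 fell to 1 against 850 (ratio 0.00411, 0.000104 to 0.0230; adjusted p = 3.65e-90, two-sided Fisher's exact test), and KTI12/HAP4 and SRP40/PTR2 to 6 and 9 against 876 and 1096. Of the 10 targets 8 were lower (9 adjusted over the list alone, with MTH1 at 4 against 41). PGM2 (7 against 49) did not pass either way, and both passed when scaled to the median ratio. The loss was not restricted to regions shared with Leu3, since the ratio was 0.105 (0.0885 to 0.124) at regions called for both factors and 0.0771 (0.0671 to 0.0881) at regions called for Gal4 and not for Leu3. Over all 104 regions called for Leu3 the ratio was 0.350 (0.320 to 0.382), with 17 lower and 9 higher of 63 tested, but the median log2 ratio was 0.11, opposite in sign. The 81 Leu3 regions not called for Gal4 had a ratio of 2.005 (1.77 to 2.27), with 9 higher and 0 lower of 40 tested, which turned to 0.983 (0.868 to 1.11) when scaled to the median ratio.

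Of 324 regions tested in that library, 67 were lower and 96 higher (35 higher and 102 lower when scaled to the median ratio), and 179 were under 0.05 before adjustment. The higher ones included MNT2/ADH4 (18 insertions against 0), CRH1/HIP1, GAB1/PAU4 and GPI2/GCR1 (12 against 0 each). Over background, MNT2/ADH4 and GAB1/PAU4 were at 3.93-fold and 4.77-fold in leu3Δ, and CRH1/HIP1 and GPI2/GCR1 were not called. Called regions numbered 7, against 71 to 91 in sef1Δ and yrm1Δ and 58 in hmo1Δ, and held 0.904% of the insertions (0.724 to 1.11).

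In hmo1Δ, insertions rose at 4 ribosomal protein gene promoters and at HMO1. RPS24B/SEC6 (chromosome IX 232369 to 233057) held 16 insertions against 1 (ratio 77.7, 12.1 to 3257; adjusted p = 4.09e-10, two-sided Fisher's exact test), and SPT6/RPS23A (chromosome VII 724764 to 726974) 31 against 7 (ratio 21.5, 9.29 to 57.8). MLP2/RPL40A and TEM1/RPS1B were at ratios of 14.6 and 12.1, and ATO3/EFT2, which holds the promoter of an elongation factor gene, at 7.28 (6 insertions against 4, 1.73 to 35.1), which did not pass the test when scaled to the median ratio. ARG82/HMO1 (chromosome IV 811632 to 812110), which holds the promoter of the deleted gene, had 35 insertions against 9 (ratio 18.9, 8.89 to 44.7; adjusted p = 1.98e-17, two-sided Fisher's exact test). Of 10 ribosomal protein regions tested, 4 rose and none fell (4 adjusted over the list alone), and the 122 regions of that list together had a ratio of 2.09 (1.74 to 2.49). The 4 that rose held 1 to 7 insertions in Gal4, so they passed the minimum of 10 through their hmo1Δ counts. The median of the 10 tested regions lay at percentile 98.6 among matched random lists. Both values therefore describe regions partly selected by a high hmo1Δ count. Over background the list was at 0.876 in hmo1Δ (0.751 to 1.02) and at 0.376 in Gal4. In leu3Δ, where Gal4 targets were at background level, the list's ratio to Gal4 was 1.94 (1.65 to 2.29), or 0.953 (0.809 to 1.12) when scaled to the median ratio. There 5 regions were higher and 2 lower of 13 tested. In sef1Δ and yrm1Δ the list's ratio was 1.04 (0.869 to 1.24) and 0.914 (0.738 to 1.12). A higher unscaled ratio was thus shared by hmo1Δ and leu3Δ but not by sef1Δ or yrm1Δ. The 4 promoters that rose in hmo1Δ held 130 to 447 per 100000 there, against 10.4 to 20.8 in leu3Δ, 0 to 28.8 in sef1Δ and 0 to 29.2 in yrm1Δ, and ARG82/HMO1 held 505 against 20.8, 43.2 and 9.73. Whether Gal4 directed these insertions was not tested.

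The Gal4 targets in hmo1Δ had a pooled ratio of 1.20 (1.12 to 1.28) but a median log2 ratio of -0.09, so the pooled value and the median differ in sign. EMP46/GAL2 (ratio 1.34, 1.21 to 1.49) and PGM2/YKU80 (2.18, 1.25 to 3.67) were higher among the 10 (2 adjusted over the list alone) and none was lower. Scaled to the median ratio, the pooled value turned to 0.993 (0.929 to 1.06) and neither region passed the test. Of 221 regions tested, 15 were higher and 3 lower (7 and 6 when scaled to the median ratio), and 38 were under 0.05 before adjustment.

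In sef1Δ, Gal4 targets were lower. The 10 targets had a pooled ratio of 0.684 (0.643 to 0.728; adjusted p = 9.43e-40 over 10 comparisons, two-sided Fisher's exact test). GAL7/GAL10 fell to a ratio of 0.547 (0.482 to 0.618), EMP46/GAL2 to 0.716 and GAL10/GAL1 to 0.804, and FUR4, GAL80 and MTH1 to 0.316, 0.364 and 0.0591. MTH1 held 1 insertion against 41 (0.00146 to 0.348). GAL7/GAL10, FUR4 and GAL80 were lower in yrm1Δ as well. PGM2, the phosphoglucomutase gene, rose to 2.52 (1.67 to 3.81), so 6 targets were lower and 1 higher (7 adjusted over the list alone). Gal4-called regions outside the targets had a ratio of 1.11 (1.07 to 1.15), with 12 higher and 4 lower of 68, which turned to 0.862 (0.833 to 0.893) when scaled to the median ratio. Regions called for Yrm1 had 1.35 (1.28 to 1.43), or 1.05 (0.993 to 1.11) when so scaled.

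Single regions that rose in sef1Δ included ACO1/STT4, next to the aconitase gene, with 41 insertions against 5 (ratio 19.9, 7.86 to 64.4; adjusted p = 2.53e-15, two-sided Fisher's exact test). BAG7/IDH2, next to an isocitrate dehydrogenase gene, held 18 against 2 (ratio 21.8, 5.22 to 194). UBP13/SEF1 (chromosome II 95882 to 100115), an interval that in the tables spans the SEF1 gene, held 18 against 0. The overlapping interval SEF1/PRX1 (chromosome II 96669 to 100371) held 0 in sef1Δ, and the tables do not show where in UBP13/SEF1 the 18 lie or how insertions in the overlap were counted. Of 252 regions tested, 28 were higher and 10 lower (17 and 21 when scaled to the median ratio), and 69 were under 0.05 before adjustment.

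In yrm1Δ, the Gal4 targets were slightly lower, with a pooled ratio of 0.922 (0.866 to 0.981; adjusted p = 0.00566 over 10 comparisons, two-sided Fisher's exact test), which turned to 1.14 (1.08 to 1.21) against the other 4 Gal4 libraries summed. That sum includes leu3Δ with its 38 target insertions, and without leu3Δ the ratio was 0.976 (0.919 to 1.04). GAL7/GAL10 (0.796), FUR4 (0.261), GAL80 (0.327) and GCY1 (0.483) were lower and none of the 10 was higher (4 adjusted over the list alone). GAL7/GAL10 turned to a log2 ratio of 0.055 against the other 4 libraries summed, and at -0.18 did not pass the test without leu3Δ in that sum. RAD54/SUT1 (chromosome VII 196403 to 198138), which holds the promoter of a sterol uptake regulator gene, rose to 38 insertions against 23 (ratio 5.41, 3.14 to 9.51; adjusted p = 1.19e-08, two-sided Fisher's exact test), and COT1/FAA1 fell to 0 against 24. Regions called for Yrm1 in its own library showed no clear pooled loss of Gal4 insertions, with a ratio of 1.19 (1.12 to 1.27), or 0.954 (0.893 to 1.02) when scaled to the median ratio. Of 46 tested, 6 were higher and 1 lower, the latter being COT1/FAA1. Losses at single regions could be missed, since 8% of simulated regions lowered to 0.25-fold passed at this depth. Of 230 regions tested, 17 were higher and 10 lower (8 and 15 when scaled to the median ratio), and 45 were under 0.05 before adjustment.

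**Figure D3:**
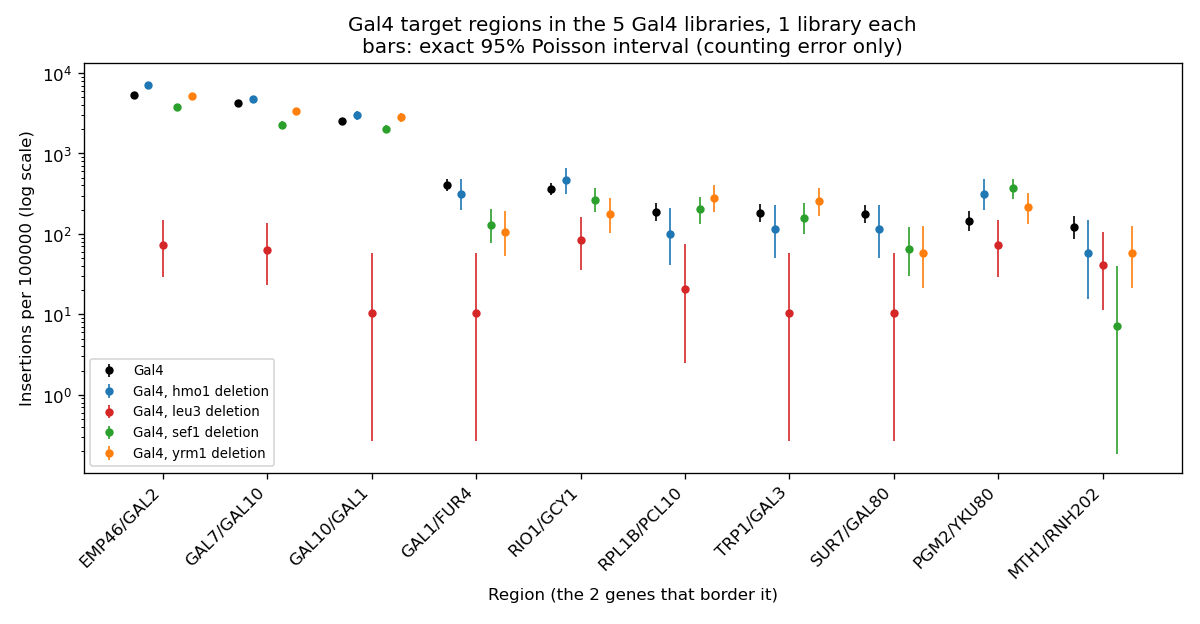
Insertions per 100000 (log axis) at the 10 Gal4 target regions in the 5 Gal4 libraries, with exact 95% Poisson intervals as bars. The library labelled leu3Δ lies lowest at each of the 10 regions except MTH1/RNH202, where sef1Δ holds 1 insertion.

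The deletion libraries also resembled each other. TIM9/MMS21 (chromosome V 117474 to 120498), PET122/OXA1 and MLF3/MSK1 fell in hmo1Δ, sef1Δ and yrm1Δ alike, for example TIM9/MMS21 from 447 insertions to 1, 13 and 7. SRP40/PTR2, the peptide transporter promoter, was higher in all 3, from 3258 per 100000 to 4010, 4034 and 4027, but scaled to the median ratio the log2 ratios were 0.031 (hmo1Δ), -0.055 (sef1Δ) and -0.015 (yrm1Δ) and none passed the test. The regions ZRG8/EDC2 (5.51 and 4.46), RPL9A/TIP20 (5.23 and 4.31) and NDE1/TIF34 (4.36 and 3.93) rose in both sef1Δ and yrm1Δ. Across 203 regions the log2 ratios of sef1Δ and yrm1Δ correlated with r = 0.659, against 0.253 for simulated unchanged libraries that share the Gal4 library, and with a covariance of 0.655 against 0.101. The values were 0.392 for hmo1Δ with sef1Δ (0.224 simulated) and 0.400 with yrm1Δ (0.204), while pairs of leu3Δ with hmo1Δ, sef1Δ and yrm1Δ had 0.0535 (0.191 simulated), 0.129 (0.255) and 0.0462 (0.226). These are correlations across regions, which are not independent replicates, and part of the excess may come from the single Gal4 library that all comparisons share.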

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

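The library labelled leu3 deletion stood apart from the other Gal4 libraries, as a difference between single libraries by Fisher's exact test in each pairing, which is not a tested difference between groups. Its share of insertions at the 10 Gal4 targets was 0.0242 of that in hmo1Δ, 0.0424 of that in sef1Δ and 0.0315 of that in yrm1Δ. Insertions were also counted in data outside the comparisons, in 8 mitochondrial and 2-micron plasmid regions where the background holds 0 insertions. These regions held 4 insertions in the Leu3 library, 10 in Yrr1, 6 in Tea1 and 4 in Cat8, which is more than the floor of 3. The background allows up to 4.39 per 100000 there, and the lower bound was 16.9 for Yrr1, 6.17 for Tea1 and 4.55 for Cat8 but 3.02 for Leu3, which is therefore not shown to differ. What produced them was not tested, nor whether the background set covered these regions. Yrm1 held 2, Lys14, Hal9 and Aro80 1 each, and Cha4, Put3, Urc2 and the 4 deletion libraries 0. For the leu3Δ library and for regions called for many factors, the explanations and tests that follow were chosen only after the result was seen, and those for regions lower in several deletion libraries were written before their tests were run.

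For the background-level insertions of the leu3Δ library at the Gal4 targets, low depth was excluded, since the upper bound of the share ratio was 0.0399. A loss limited to regions called for Leu3 was excluded as well, with an upper bound of 0.0881 at Gal4 regions not called for Leu3. Leu3 may still occupy regions that did not pass the threshold for a call. The library does not hold another factor of this series, since its fold at the strongest regions of each of the other 11 factors was bounded by 0.231 of that factor's own fold (Put3 came closest). The share of its insertions distributed as in the Gal4 library was -0.462% (-1.40 to 0.541), which would fit a library without a working Gal4 fusion or with a wrong label, while in hmo1Δ, sef1Δ and yrm1Δ it was 108%, 97.6% and 101%. A dependence of Gal4 on Leu3 at every target would give the same value, and with 1 library and a strain name that changes with the deletion these cannot be told apart. Ty5 itself was under the GAL1/10 promoter in strains without chromosomal GAL4, and this library still held 9628 insertions. Whether the Gal4 fusion drove that transcription was not tested.

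For the 22 regions called for 5 or more factors, called regions were shuffled within 58 classes of background and length. This gave at most 5 such regions in 1000 shuffles (mean 1.28), so background and length as classed did not account for the number. The 22 lay at percentiles 84.9 to 99.6 of background insertions. Regions within a class still differ in background, so an effect of the highest backgrounds is not excluded. A transposon preference common to all libraries that the background set misses could neither be excluded nor shown. At these regions 2 of 12 factor libraries, Lys14 (fold 1.53) and Cha4 (1.501), lay with their upper bound under 2.09, which is 0.5 times the median fold, where at least 3 were required to exclude it. The leu3Δ library had a fold of 1.05 (0.861 to 1.26) there. Whether a shared DNA site draws these factors together was not tested.

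TIM9/MMS21, PET122/OXA1 and MLF3/MSK1 were lower than in Gal4 in hmo1Δ, sef1Δ and yrm1Δ alike, and their background counts were not raised in the Gal4 table. Background counts do not enter Fisher's test, so this comparison cannot exclude another build or region set of the Gal4 table as a cause. The ratio of background shares at these regions between the tables was 0.858 with an upper bound of 1.22, while the Gal4 library held 6.97 times (5.59 to 8.79) the share of the 3 deletion libraries. Whether the Gal4 library's own insertions were mapped or assigned to regions otherwise was not tested, and background counts cannot show it. Counting error in the shared Gal4 library was excluded, since 3 such regions were found against at most 0 in 100 simulations. A jackpot of PCR or of early insertion in the single Gal4 library might still explain them, and no biological explanation was tested.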

How the results depend on the processing

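Each result has 1 library behind it, so these alternatives measure choices of processing and not replication. Of the summary results to which each alternative applied, all kept their direction and threshold side, or a count within 1.5 times, without a minimum of insertions for calls (16 results), without plasmid-borne and strain marker loci (10), without plasmid-borne regions in lists (13), without regions differing by over 20 bp in length (8), with totals that exclude the Gal4 targets (21) and, for overlaps, after thinning to the shallowest factor library (2). The Poisson p of the authors, the wider regions, the sum of other libraries without leu3Δ (for regions and for lists), the limited list, the length filter and the median of ratios for lists were added after the data were seen. The alternatives for binding-site sequences were not run. Single regions that lost or gained their call numbered most against the other 4 Gal4 libraries summed (20 weaker, 4 stronger, 2 turned and 78 unchanged) and without leu3Δ in that sum (20 weaker, 1 stronger and 56 unchanged). For the values that follow the cause was not tested, except that thinning, stricter thresholds and other minima change the number of insertions or regions tested by construction.

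Thinned to the shallowest library with an own Poisson test, called regions numbered 73 for Yrm1, 28 for Lys14, 36 for Cat8, 17 for Put3, 24 for Urc2, 64 for Hal9 and 36 for Aro80. With the authors' Poisson p they numbered 109 for Cat8, 72 for Put3, 93 for Urc2, 103 for Aro80 and 23 for leu3Δ, and with an own Poisson test 55 for Put3 and 12 for leu3Δ. In leu3Δ 3 calls were left at an authors' p of 0.0001, 0 after Benjamini-Hochberg adjustment and 4 with at least 10 insertions. Without the 10% of regions with the most background insertions, 7 Gal4 regions were shared with another factor and 24 were shared by Yrm1 and Yrr1.

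In the deletion libraries without a minimum, 8 regions were higher in hmo1Δ, 230 higher in leu3Δ and 6 lower in yrm1Δ, and with at least 20 insertions 17 were higher in leu3Δ. With the median of ratios, 7 were higher and 6 lower in hmo1Δ, 35 and 102 in leu3Δ, 17 and 21 in sef1Δ, and 8 higher in yrm1Δ. Thinned to the shallowest of the 5 libraries, 8 were higher in hmo1Δ, 14 higher in leu3Δ, 6 lower in sef1Δ, and 7 higher and 6 lower in yrm1Δ. With wider regions, 5 were lower in hmo1Δ and 16 lower in sef1Δ. Against the other 4 libraries summed, 145 were higher in leu3Δ, 5 lower in sef1Δ and 3 lower in yrm1Δ, and without leu3Δ in that sum 9 were higher and 5 lower in hmo1Δ and 7 higher and 5 lower in yrm1Δ.

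Against the other 4 libraries summed, yrm1Δ turned at GAL7/GAL10 (log2 0.055), at EMP46/GAL2 (0.26) and at the pooled Gal4 targets (ratio 1.14, 1.08 to 1.21). Without leu3Δ in that sum, the yrm1Δ ratio at the Gal4 targets was 0.976 (0.919 to 1.04), no longer past 1. With the median of ratios, the Gal4 targets in hmo1Δ turned to 0.993 (0.929 to 1.06) the Yrm1-called regions in yrm1Δ to 0.954 (0.893 to 1.02), the Gal4-called regions outside the targets in sef1Δ to 0.862 (0.833 to 0.893), the Leu3-called regions not called for Gal4 in leu3Δ to 0.983 (0.868 to 1.11), the ribosomal protein genes in leu3Δ to 0.953 (0.809 to 1.12) and SRP40/PTR2 to log2 -0.055 in sef1Δ and -0.015 in yrm1Δ. The Yrm1-called regions in sef1Δ weakened to 1.05 (0.993 to 1.11). With the list limited to regions called in the Gal4 library, the ribosomal protein list came down to 1 region, RHO5/RPS3, chosen by its high Gal4 count. Its values of 0.855 (0.535 to 1.31) in hmo1Δ and 0.221 (0.0992 to 0.432) in leu3Δ lie on the other side of 1 and say nothing about the list.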

Other observations

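Wider gene families, some of which contain the factors' own targets, also differed between libraries. The 15 pleiotropic drug resistance regions, which hold transporter genes such as PDR5 and include Yrm1 and Yrr1 targets such as SNQ2, were at 14.0-fold over background for Yrm1 (12.8 to 15.4), 19.99-fold for Yrr1 (18.3 to 21.9) and 15.9-fold for Hal9 (14.5 to 17.5), where TPO1 held most, against 0.703 to 1.19 in the other factor libraries. Regions of branched-chain and lysine amino acid synthesis, which include most Leu3 and all Lys14 targets, were at 24.5-fold for Lys14, 9.64-fold for Leu3 and 4.17-fold for Tea1, the last with HMS2/BAT2. Ribosomal protein regions were low for Gal4 (0.376), Yrm1 (0.503), Tea1 (0.524) and Leu3 (0.596). For Yrr1 they were at 1.78 pooled (1.67 to 1.89) with a median log2 fold of -1.60, opposite in sign, because IME1/RPL43B alone held 1169 insertions. Glycolysis regions lay between 0.515 (Yrr1) and 0.822 (Put3) in the factor libraries, hexose transporter regions between 0.557 (Leu3) and 1.62 (Yrr1), and core histone regions between 0.238 (Yrm1) and 1.05 (Cat8). Subtelomeric families such as PAU and COS were lowest in sef1Δ (0.0416) and Gal4 (0.0977) and at 0.929 (0.703 to 1.21) in leu3Δ.

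Regions of the tagged factors' own genes were above background for Aro80 (3.53, 2.58 to 4.83), with HKR1/ARO80 at 42.4-fold, and between 0.101 (yrm1Δ) and 1.73 (leu3Δ) in the other libraries. Regions of the deleted factors' genes were at 10.2-fold in hmo1Δ (6.34 to 16.2), through ARG82/HMO1, and at 1.98 or less in the others. Strain marker loci were at 37.4-fold for Lys14 through LYS2, 3.11-fold for Hal9 through EXG1/MET17, and at 1.77 or less elsewhere. Plasmid-borne sequences were at 24.2-fold for Gal4, 25.3-fold in hmo1Δ, 17.6-fold in sef1Δ and 23.0-fold in yrm1Δ through GAL10/GAL1, and at 2.57 or less elsewhere.

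Called regions lay close to the strongest region of the same library for some factors, and the hypothesis that insertions spread along the chromosome from the strongest site was formed and tested after this was seen. Over the 12 factor libraries, 40 called regions lay within 25 kb of the library's strongest shared region, against 11 at most when strongest regions were exchanged between libraries in 11 shifts, so the hypothesis could hold. Put3 had 12 of them around PUT1, Tea1 7 around GLN1, Cha4 6 around CHA1, Aro80 5 around ESBP6 and Hal9 4 around TPO1, while Gal4, Yrm1, Yrr1 and Urc2 had 0. The region used was SRT1/YPK2 for Yrm1, LYS2/TKL2 for Lys14 and ESBP6/NAF1 for Aro80. RGI2/VHR1, YDL183C/LYS20 and YDR379C-A/ARO10 held more insertions in these libraries, and their surroundings were not counted. The Put3 fold fell from 17.7 within 5 kb to 6.92 at 5 to 25 kb and 1.76 at 25 to 100 kb, and for Aro80 from 4.25 at 5 to 25 kb to 1.08 at 25 to 100 kb. Clustered binding sites of a factor would give the same count.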
